A study of Mus musculus with 7 samples.

How the data were processed

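RNA was measured by sequencing in skin of 7 mice of one genotype, hk14SCF/HRM. Per the labels' protocols, RNA was extracted with a column kit for fibrous tissue and the libraries were made with SMART-Seq v4, a kit that copies full-length transcripts and does not mark the strand. The software DRAGEN and the mouse genome build mm39 are named in the submitters' processing notes. The role and version of DRAGEN, the annotation release and any filter are not given in the sources used here.

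The authors deposited 1 workbook with 2 sheets. By its rows, the first sheet holds 55414 genes. Per the file headers, it has 12 columns of counts and 12 columns of TPM, and each gene's position, length, type and functional annotation. The second sheet holds 18 of these genes under 3 headings, with 12 columns of counts and 7 of TPM. The libraries in both sheets carry a project code and a running number, whereas the 7 samples carry titles with the group and mouse number, and library names with another running number.

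A column was assigned to a sample only where its name matched the labels of that sample and of no other. No column met this condition, with 0 of 12 libraries matched. The table holds 5 more libraries than there are samples. Whether these are other mice or repeat libraries of the same mice is not given in the sources used here. The second sheet gives TPM for 7 of the libraries, the same number as the samples. These may be the submitters' selection of the 7 mice, which a pairing by running number alone does not take into account. Their names do not state which mouse each belongs to. The 24 columns of per-sample values in the first sheet and the 19 in the second were therefore not used. No expression value, depth, fold change or test is given for any group.

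The tests fixed before the data were examined compared the 3 induced mice with the 4 control mice, each week with the controls, and the weeks with each other. None of them was run, and neither were their alternatives. The gene positions and lengths, which belong to no sample, were read from the authors' deposited annotation columns with Python 3.11.15. For 35 gene lists, fixed at the same time, members were looked up by symbol in the gene name column. Older symbols were matched by gene identifier through a reference of gene names. The lists cover cell types of skin and other tissues, immune and stress responses, signalling, the cell cycle, and mitochondrial and sex genes.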

Results

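Skin was collected from 7 mice that carry the hk14SCF transgene on a hairless (HRM) background. The transgene places stem cell factor, the ligand of the receptor Kit on melanocytes, under a human keratin 14 promoter. The groups comprised 4 mice without treatment, 2 mice at 7 weeks after induction of vitiligo and 1 mouse at 12 weeks. Vitiligo was induced by transfer of CD8 T cells from PMEL mice, whose T cell receptor recognises the melanocyte protein gp100, together with dendritic cells grown from bone marrow and loaded with the human gp100 peptide. The design compares induced with untreated skin and, with 1 mouse at the later time, 12 weeks with 7 weeks.

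The gene table covered 55414 genes, of which 21884 were annotated as protein-coding, in 12 libraries. None of the 12 library names matched the labels of any of the 7 mice, so no library was assigned to a group. For this reason no expression level and no difference between groups is reported for any gene, and the depth per mouse is not given.

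The submitters set 18 genes apart on a second sheet. The cytokine heading held 6 genes, namely Il4, Il6, Il10, Il15, Il17a and Ifng. Among them, Ifng encodes interferon gamma and lies on chromosome 10 from 118276951 to 118281797 (mm39, plus strand). Il15, which encodes a cytokine that sustains memory CD8 T cells, lies on chromosome 8 from 83058261 to 83129851 on the minus strand. A further 5 genes stood under a chemokine heading, namely Ccl5, Ccl20, Cxcl9, Cxcl10 and Cxcl11. Cxcl9, Cxcl10 and Cxcl11 lay close together on chromosome 5 between 92469206 and 92513344, all on the minus strand. Cxcl9 and Cxcl10 encode ligands of the receptor Cxcr3. Cxcl11 was annotated as a polymorphic pseudogene, so whether it encodes a ligand in these mice is not known.

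The remaining heading, for other markers, held 7 genes. Cat, Sod1, Sod2 and Sod3 encode catalase and the superoxide dismutases, enzymes that remove reactive oxygen species. Mlana, Tyr and Dct are genes of pigment cells: Tyr encodes tyrosinase, the rate-limiting enzyme of melanin synthesis, and Dct encodes dopachrome tautomerase. In the mm39 annotation, Mlana lay on chromosome 19 from 29675224 to 29686034 on the plus strand. Tyr lay on chromosome 7 from 87073979 to 87142720 and Dct on chromosome 14 from 118250202 to 118289656, both on the minus strand. These are the submitters' choices, and no expression value of these genes is reported.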

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

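No result on expression was obtained. The match of libraries to mice, on which this rests, depended on the rule: 0 libraries were matched by whole name, and 2 other rules, chosen after seeing the data, gave other counts. By the running number alone, 7 libraries were paired with the 7 mice. By the order of the 7 TPM columns on the second sheet, 7 were paired as well. The assignments disagreed: 0 of the 7 mice received the same library in both, and of the 3 libraries present in both, 1 fell in the same group. Neither was used, because a number or an order does not identify a mouse. The values on the second sheet, those of the pigment genes included, were seen when the sheet was inspected. They were neither tested nor used to choose between the rules, because pigment cell loss is the outcome that the design compares, and groups set by it would fix the comparison. Of 462 symbols in the lists, 456 stood as written in the gene name column, and 458 had a row when older symbols were allowed. Symbols and not genes are counted: the lists hold both Loricrin and Lor, and only Lor had a row. No paired analysis was possible because no library was matched to a mouse. The labels tie the mouse numbers to no shared litter, batch or day, so they would not in themselves pair control with induced mice. The alternative normalizations, filters, tests and fits without single mice were not run, since no library was assigned to a group.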
